A study of Danio rerio with 4 samples.

How the data were processed

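Poly-A selected RNA libraries were made from whole zebrafish embryos and sequenced on an Illumina instrument as paired reads of 150 bp, per the labels' protocols, from about 500 ng of total RNA each. Fertilization was limited to a window of 15 min and embryos were cleaned at about 6 h and kept at about 30 per dish. There were 4 libraries, 2 of quadruple mutants (mdm2, puma, noxa and p21) and 2 of siblings with the same puma, noxa and p21 mutations and 1 or 2 intact mdm2 copies. Genotype and replicate number were taken from the labels. Titles also call the quadruple mutants abnormal and the siblings normal, so genotype and that description cannot be told apart. Titles and design give 18 hpf and the tissue label gives 30 hpf.

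The deposited values were TPM for 32057 Ensembl gene identifiers with 2 decimals, and each library summed to 1e+06 within rounding. The submitters' processing notes name STAR 2.7.3a, HTSeq 0.12.3, RSEM 1.3.3, DESeq2 1.42.1, R 4.3.3 and the genome build GRCz11. Which of these tools produced the TPM, with which gene annotation and strand setting, is not given in the sources used here. TPM divides by transcript length and by the library total, so it keeps no depth. Counting error per gene is therefore unknown, no count model was used, and no counting interval or detection floor was computed. A rise in some abundant genes lowers the TPM of the others, which the rescaled alternatives address. Reads shared between near-identical copies, overlapping genes or antisense partners could have been divided in ways the values do not show.

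Identifiers were matched to a table of gene names, which named 28988 of them and left 3069 without a symbol; 5966 identifiers shared a symbol with another. The table mixes zebrafish and capitalised human symbols, and symbols are printed in lower case, with the Ensembl identifier where a symbol is shared. Members of a list were matched exactly, then regardless of case, then by the human symbol without the zebrafish copy letter, and symbols with more than 4 identifiers were left out. GC content and gene length were not analysed here. Gene order in a RefSeq gene table of assembly GRCz12tu served only to find which genes neighbour mdm2 and to form windows of the same size elsewhere.

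Genes with at least 1 TPM in at least 2 libraries were tested (16172 genes). log2(TPM + 1) values were fitted with limma 3.58.1 in R 4.3.3, with a variance trend (prior degrees of freedom 3.91, residual degrees of freedom 2), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 changes are quadruple mutant minus sibling control on the log2(TPM + 1) scale, which understates the change of low genes. Unless stated otherwise an adjusted p is from this test. A gene listed at 0 in a genotype may be a failed estimate and is given no fold.

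The comparison, the test, 24 gene lists with 699 distinct symbols, the rule for named genes and the alternatives were fixed before the data were examined. Of the lists, 2 hold the mutated and title genes and 22 were tested with camera (preset correlation 0.01) against all other tested genes, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated for each list and fry were run beside it. Named genes were the mutated and title genes, the 12 largest changes in each direction among genes with an adjusted p under 0.05, a mean of at least 5 TPM in the higher genotype, no overlap between genotypes and a symbol that is not a clone name, and for each list up to 4 members with the lowest p. Other genes are named where a count is small, and are said to be chosen after their values were seen. Some genes that the rule takes are not reported here. Medians of lists were compared within each library, with each gene set against its control mean, in comparisons chosen after the medians were seen. The control values of such a comparison therefore mirror each other by construction and show only the spread between the controls. A 2-sided permutation test over genes used 1e+05 resamples. These steps used Python 3.11.15 (numpy 2.4.6, pandas 2.3.3), and figures were drawn with matplotlib 3.10.9.

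Alternatives were pseudocounts of 0.1 and 5 TPM, no filter on low values, a filter of 5 TPM, median ratio scaling, quantile normalization, no variance trend, a replicate block, a minimum fold of 2, an estimated correlation for the lists, and each library left out in turn. In the last case the genotype with 1 library was assumed to vary like the other. The filter was applied again to the remaining libraries. Genes under 1 TPM throughout a genotype were then untested without either library of the other genotype. The limma test was tested on simulated data for the comparison of quadruple mutant with sibling control. In 5 simulations with 200 changed genes among 15671, it recovered 93.2% of genes changed 2-fold and 99.2% of those changed 4-fold, with 5.39% of calls false and 100% of signs right. The changed genes lay above a mean of about 5 TPM, as many up as down, with noise drawn from the fitted variance trend. In the data 65.6% of tested genes were called, so these rates do not carry over to this comparison.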

Results

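Whole zebrafish embryos were profiled by poly-A RNA sequencing in 4 libraries from 2 genotypes, with 2 libraries per genotype. The quadruple mutants were homozygous for mutations in mdm2, puma (bbc3), noxa (pmaip1) and p21 (cdkn1a). Mdm2 is the ubiquitin ligase that restrains p53, puma and noxa are pro-apoptotic p53 targets, and p21 is a cyclin-dependent kinase inhibitor induced by p53. Their siblings carried the same puma, noxa and p21 mutations with at least 1 intact copy of mdm2, and served as controls. The comparison therefore asked which transcripts differ after loss of mdm2 in embryos that lack puma, noxa and p21, in a study of the genes through which p53 arrests the cell cycle. Sample titles also call the mutants abnormal and the siblings normal, so genotype and that description cannot be told apart. Titles and design place collection at 18 hours post-fertilization (hpf), whereas the tissue label reads 30 hpf, and the age was not settled from the labels. Values were TPM (transcript abundance corrected for transcript length) and were scaled to the same total in each library, so that sequencing depth is unknown. Between 15242 and 15584 genes reached 1 TPM per library.

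Each of the genes mutated in the design had more transcript in the quadruple mutants. mdm2 (ENSDARG00000033443) stood at 1634 and 1819 TPM in the mutant libraries against 81.9 and 85.1 TPM in the controls, a log2 change of 4.35 (SE 0.065, limma adjusted p = 1.4e-06). Transcripts of bbc3 (ENSDARG00000069282) were at 25.6 and 28.0 TPM against 0.99 and 1.28 TPM (log2 change 3.70, SE 0.119). For pmaip1 (ENSDARG00000089307) the values were 24.5 and 23.6 TPM against 2.49 and 2.17 TPM (2.91, SE 0.103), and for cdkn1a (ENSDARG00000076554) 28.9 and 29.8 TPM against 3.67 and 4.86 TPM (2.54, SE 0.128). Gene-level TPM counts transcripts of mutant and intact alleles alike, so these values do not check the genotype labels.

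The other 3 genes of the series title rose as well. ccng1 (ENSDARG00000076667), which encodes cyclin G1, was among the more abundant transcripts and went from 413 ± 8.92 TPM to 3427 ± 206 TPM (SD, n = 2 per genotype; log2 change 3.05, SE 0.056, adjusted p = 2.1e-06). foxo3b (ENSDARG00000042904), a forkhead transcription factor gene, went from 8.18 ± 0.424 TPM to 271 ± 8.16 TPM (4.89, SE 0.068, adjusted p = 1.4e-06). fbxw7 (ENSDARG00000060994), the substrate receptor of a ubiquitin ligase that acts on cyclin E, went from 20.8 ± 0.594 TPM to 103 ± 5.25 TPM (2.25, SE 0.070, adjusted p = 7.1e-06). With cdkn1a, all 4 title genes passed, as did 4 adjusted over the list alone; the study chose these genes, so their count is not independent evidence.

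**Figure D1:**
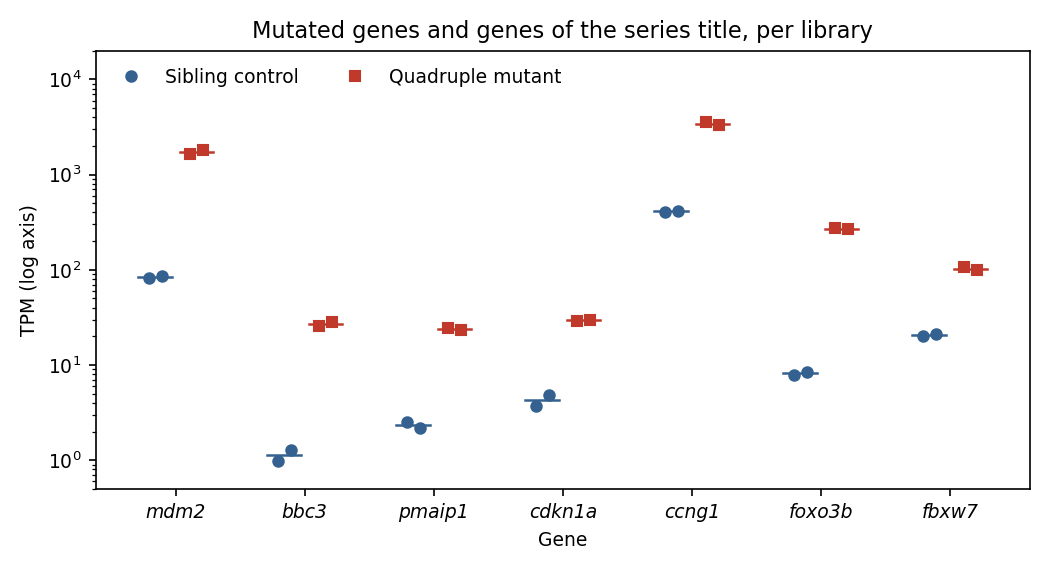
TPM of the mutated genes and the title genes in each of the 4 libraries, on a log axis; each point is 1 library, short lines mark the means of 2 libraries, with quadruple mutants and sibling controls in separate colours. For each of the 7 genes both mutant libraries lie above both controls, from fbxw7 with a log2 change of 2.25 to foxo3b with 4.89.

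Across the transcriptome, 4522 genes were higher and 6091 lower in the quadruple mutants among 16172 genes tested, or 65.6% of them. With a fold change of at least 2 on the log2(TPM + 1) scale, 1543 were higher and 1854 lower. Among named genes with a mean of at least 5 TPM in the higher genotype, the largest rise was that of cdkn2a/b, an inhibitor of the G1 cyclin-dependent kinases, from 0.49 ± 0.269 TPM to 199 ± 11.6 TPM (log2 change 7.08, SE 0.137, adjusted p = 2.2e-06). It was followed by gadd45a (ENSDARG00000043581), a growth arrest and DNA damage gene, at 420 ± 10.6 TPM against 5.17 ± 0.219 TPM (6.09, SE 0.065). The p53 target phlda3 rose from 12.4 ± 3.10 TPM to a mean of 600 TPM (5.51, SE 0.149). Immune genes were among the 12 largest rises, with log2 changes of 5.27 for the chemokine receptor gene cxcr3, 5.24 for the ubiquitin-like interferon response gene isg15 and 5.24 for irg1l. The others were tnfaip6 (5.71), rpz5 (5.66), rgs20 (5.39), ace (5.23), cpn1 (ENSDARG00000096720; 5.71) and rgs5b, which was listed at 0 in both controls and at 39.1 and 36.7 TPM in the mutants. The value of cpn1 depended on which control was kept, at 4.92 without control replicate 1 and 6.50 without control replicate 2.

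The 12 largest falls by the same criteria included genes of DNA replication and of the maintenance of DNA methylation. The replicative helicase genes mcm5, mcm2 and mcm3 fell by 3.23 (SE 0.218), 3.18 (SE 0.208) and 3.14 (SE 0.175) on the log2 scale, mcm5 from 176 ± 1.63 TPM to 18.5 ± 6.77 TPM. The chromatin genes cdca7 (-3.46, SE 0.275) and hells (-3.41, SE 0.252) and the maintenance methylation genes uhrf1 (-3.16, SE 0.116) and dnmt1 (-3.08, SE 0.169) fell by similar amounts. The fatty acid binding protein gene fabp3 fell by 3.10, nmnat3 by 3.27 and the glucose transporter gene slc2a1 (ENSDARG00000001437) by 3.16. The small nucleolar RNA u3 (ENSDARG00000115704) was the least certain, at 0 and 6.28 TPM in the mutants against 29.5 and 15.7 TPM in the controls (-3.06, SE 0.876, adjusted p = 0.023). Without mutant replicate 1 its log2 change was -1.63, without mutant replicate 2 it was -4.50, and without control replicate 1 its adjusted p was 0.0875.

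Both mutant libraries lay on the same side of both controls for every gene called by limma, and for 83.3% of all tested genes, where chance gives 33.3%. An exact permutation test of 2 against 2 libraries cannot go below p = 0.333, so the calls rest on the spread that limma shares between genes. Pearson's r across genes was 0.991 between the mutant libraries, 0.993 between the controls and 0.878 to 0.890 between genotypes. The median log2 change of all tested genes was -0.10, against which the gene lists are read; median ratio scaling moved it to 0.000443. The genes that were higher held 31.7% of all TPM in the mutants and 18.2% in the controls. Nothing in the labels says that the libraries came from separate clutches, so p-values measure only the spread between these samples, which may be technical.

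Among textbook transcriptional targets of p53, 30 of 41 tested members rose, 6 fell and 5 did not pass (31 and 6 adjusted over the list alone; median log2 change 1.37, camera adjusted p = 8.19e-09). The adjusted p was 0.322 with an estimated correlation. After gadd45a, the lowest p-values belonged to sesn1 (354 ± 12.8 TPM against 17.4 ± 0.332 TPM, log2 change 4.27), sesn3 (602 ± 11.8 TPM against 26.6 ± 1.92 TPM, 4.45) and mdm2. The sestrins restrain growth signalling through mTORC1. Members that fell, chosen after their values were seen, were ccng2 (-1.45), the nucleotide excision repair genes xpc (-1.11) and ddb2 (-0.98), tp53i11 (ENSDARG00000069430; -0.98), triap1 (-0.82) and 1 copy of ppm1d (ENSDARG00000009273; -0.37). Those that did not pass were fdxr (-0.23), the other ppm1d (ENSDARG00000021380; 0.00), perp (0.08), plk2 (ENSDARG00000019130; 0.27) and tigarb (0.31). The list holds 5 genes that the study mutated or named, mdm2, ccng1, bbc3, pmaip1 and cdkn1a.

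Among negative regulators of the cell cycle, 19 of 34 members rose, 10 fell and 5 did not pass (19 and 11 adjusted over the list alone; median 0.69, camera adjusted p = 0.00267, and adjusted p = 0.322 with an estimated correlation). The lowest p-values among the risers were those of gadd45a, foxo3b, ccng1 and cdkn2a/b, of which foxo3b and ccng1, like fbxw7 and cdkn1a in the same list, were the study's choice. The list shares gadd45a, gadd45b, ccng1, btg2 and cdkn1a, which rose, and ccng2, which fell, with the p53 targets. The calls of both lists are therefore not separate evidence. Of members chosen after their values were seen, the pocket protein gene rbl2 rose by 4.15 (SE 0.126), and the kinase inhibitor gene cdkn1b (ENSDARG00000029018) rose by 3.26 (SE 0.070) to 171 ± 8.85 TPM. The checkpoint kinase genes chek1 (-2.30) and chek2 (-1.69) and the pocket protein gene rbl1 (-1.66) fell. Values of the members that did not pass were -0.29 for pkmyt1, -0.06 for wee1, 0.01 for tob1b, 0.02 for cdkn2c and 0.32 for foxo1 (ENSDARG00000099555).

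Of 29 core apoptosis genes, 19 rose, 5 fell and 5 did not pass, in embryos labelled mutant for puma and noxa in both genotypes (19 and 5 adjusted over the list alone; median 0.76, camera adjusted p = 4.07e-05, and adjusted p = 0.322 with an estimated correlation). The pore-forming effector gene bax rose from 34.9 ± 0.580 TPM to 283 ± 5.76 TPM (log2 change 2.98, SE 0.055), and casp8, the initiator caspase of the death receptor pathway, from 4.40 ± 0.495 TPM to 143 ± 7.83 TPM (4.74, SE 0.093). The anti-apoptotic gene bcl2l1 also rose, by 1.74 (SE 0.061), and the list includes bbc3 and pmaip1, which the study mutated. With bax, casp8 and apaf1, which rose too, these are also in the p53 target list, so the calls of both lists are not separate evidence. The members that fell were bcl2a (-0.86), casp2 (-0.81), bok (ENSDARG00000008807; -0.53), bida (-0.37) and mcl1a (-0.27), and those that did not pass included xiap (-0.13), bcl2l10 (-0.08), cflara (0.08) and casp6 (0.15), all named after their values were seen. The number of members that fell was 3 under median ratio scaling, 2 without control replicate 1 and 1 without control replicate 2.

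Of 56 G1/S and replication genes, 54 fell, 0 rose and 2 did not pass (54 and 0 adjusted over the list alone; median log2 change -2.15, camera adjusted p = 4.87e-16, and adjusted p = 0.328 with an estimated correlation). The helicase gene mcm7 fell from 546 ± 3.44 TPM to 74.5 ± 6.74 TPM (-2.86, SE 0.072), the origin licensing gene cdc6 from 40.4 ± 2.28 TPM to 6.50 ± 0.403 TPM (-2.47, SE 0.090) and the single-strand binding gene rpa3 from 123 ± 4.99 TPM to 31.0 ± 2.16 TPM (-1.96, SE 0.074). The 2 genes that did not pass, named after their values were seen, were low copies, rrm2 (ENSDARG00000020711; 0.83 against 1.84 TPM) and mcm6 (ENSDARG00000033231; 1.66 against 1.90 TPM). Mutant library 2 lay above mutant library 1 in 51 of the 56 members, by a median of 0.26 on the log2 scale.

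Of 49 G2/M and mitosis genes, 47 fell and 2 rose (47 and 2 adjusted over the list alone; median -1.65, camera adjusted p = 3.88e-12, and adjusted p = 0.328 with an estimated correlation). The spindle assembly factor gene tpx2 fell from 157 ± 0.601 TPM to 38.4 ± 0.573 TPM (-2.01, SE 0.056), the spindle motor gene kif11 by 1.68 (SE 0.069) and the transcription factor gene mybl2 by 2.17 (SE 0.089). Against the rest of the list, ect2, an activator of RhoA in cytokinesis, rose from 12.6 ± 0.247 TPM to 176 ± 7.11 TPM (3.71, SE 0.066). The phosphatase gene cdc25d, named after its values were seen, rose from 0.07 and 0.24 TPM to 8.09 and 8.62 TPM (3.02, SE 0.134). With either mutant library left out, cdc25d, under 1 TPM in both controls, could not meet the filter and was not tested. In a comparison chosen after the medians were seen, replication minus mitosis medians were -0.62 and -0.45 in mutant libraries 1 and 2. The control values, -0.00279 and 0.00279, mirror each other by construction.

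Of 44 DNA damage response and repair genes, 34 fell, 1 rose and 9 did not pass (34 and 1 adjusted over the list alone; median -1.12, camera adjusted p = 3.07e-07, and adjusted p = 0.328 with an estimated correlation). The mismatch repair gene msh6 fell by 2.94 (SE 0.146), the endonuclease gene mre11 by 1.93 (SE 0.102) and the base excision repair gene apex1 by 1.22 (SE 0.051). The riser, named after its values were seen, was atrip (0.92), the partner of the checkpoint kinase ATR. Ribosome biogenesis genes moved in the same direction, with 42 of 46 lower, 3 higher and 1 not past the test (42 and 3 adjusted over the list alone; median -0.96, camera adjusted p = 1.78e-09, and adjusted p = 0.328 with an estimated correlation). The nucleolar genes ncl (-1.27, SE 0.050), dkc1 (-1.36, SE 0.056) and nop58 (-1.28, SE 0.065) fell. The exceptions, named after their values were seen, were ddx56 (0.58), utp4 (0.54) and heatr1 (0.25), which rose, and myc (ENSDARG00000007241; -0.13). Of 20 glycolysis genes, 4 rose, 11 fell and 5 did not pass (4 and 11 adjusted over the list alone), and the list did not pass (median -0.33, camera adjusted p = 0.122). Its copies went both ways, as aldoc (ENSDARG00000019702) rose by 2.59 and hk1 by 0.97 while aldoa (ENSDARG00000011665) fell by 0.85. The other risers, named after their values were seen, were hk2 (0.53) and slc2a1 (ENSDARG00000007412; 0.83), and the members that did not pass were eno1 (ENSDARG00000022456; -0.36), tpi1 (ENSDARG00000025012; -0.31), gpi (ENSDARG00000012987; -0.24), pgam1b (-0.15) and pdk1 (0.13).

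**Figure D2:**
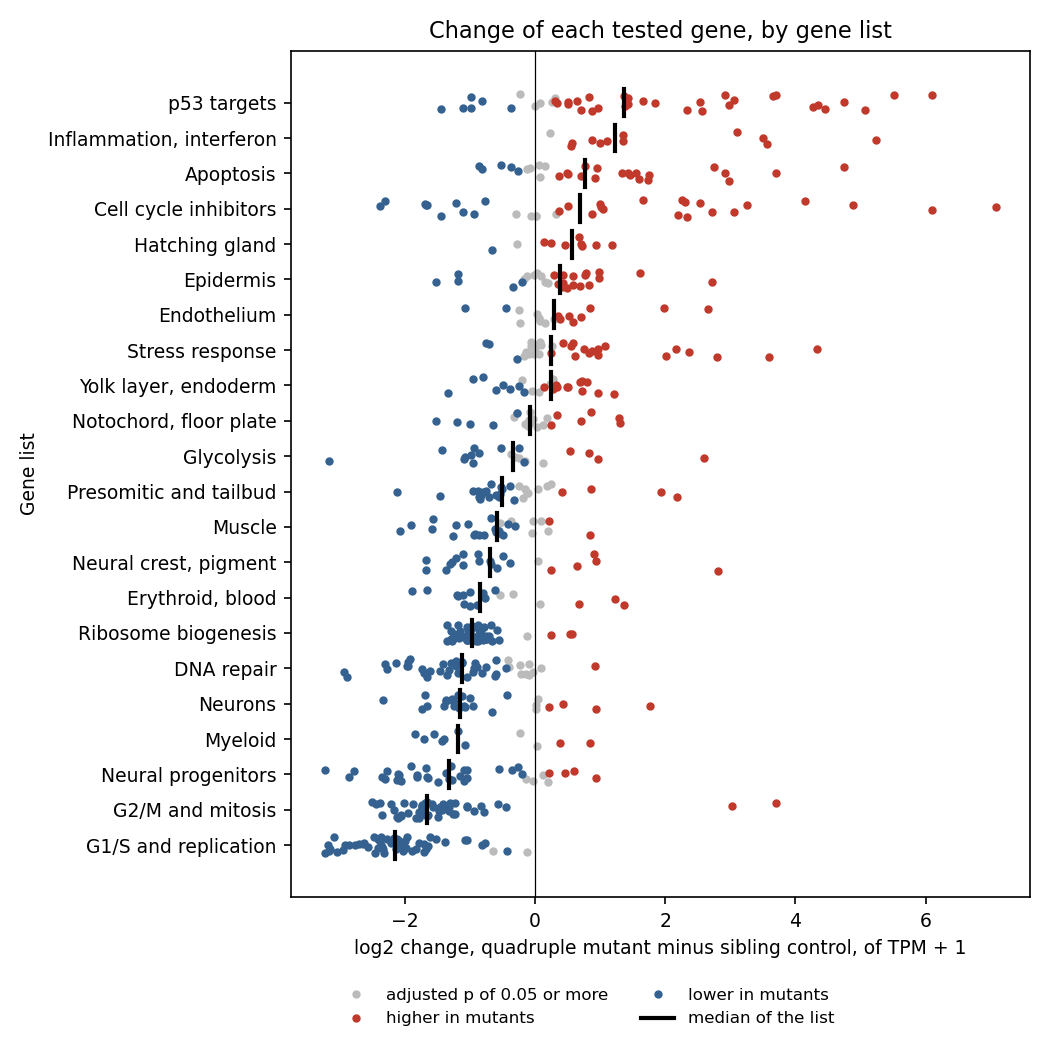
Log2 change of TPM + 1 (quadruple mutant minus sibling control) for each tested gene of the 22 tested lists; each point is 1 gene, coloured by whether it was higher, lower or not past an adjusted p of 0.05, and each black bar is the median of a list. Medians run from 1.37 for the p53 targets to -2.15 for the G1/S and replication genes, and ect2 and cdc25d are the points to the right of 0 among the G2/M genes.

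Of 39 neural progenitor genes, 31 fell, 4 rose and 4 did not pass (31 and 4 adjusted over the list alone; median -1.33, camera adjusted p = 2.47e-05, and adjusted p = 0.328 with an estimated correlation). The radial glial gene fabp7 (ENSDARG00000007697) fell from 40.1 ± 1.82 TPM to 4.71 ± 0.658 TPM (-2.85, SE 0.109), the proneural gene ascl1b from 21.2 and 20.9 TPM to 4.05 and 4.24 TPM and the retinal homeobox gene rx1 by 2.12 (SE 0.116). Risers named after their values were seen were notch3 (0.22), zic2 (ENSDARG00000037178; 0.45), the other fabp7 (ENSDARG00000034650; 0.59) and pax7 (ENSDARG00000070818; 0.94), of which 2 were counted with either control left out. Those that did not pass were 2 copies of notch1 (ENSDARG00000103554, -0.14; ENSDARG00000052094, 0.20), pax3 (ENSDARG00000010192; -0.03) and six3 (ENSDARG00000054879; 0.12). Of 28 neuron genes, 21 fell, 4 rose and 3 did not pass (21 and 4 adjusted over the list alone; median -1.15, camera adjusted p = 0.00224, and adjusted p = 0.328 with an estimated correlation). The neurogenic factor genes neurod4 (-2.33, SE 0.144) and neurod1 (-1.74, SE 0.108) and the pan-neuronal gene elavl3 (-1.17, SE 0.075) fell. Risers named after their values were seen were dlx2 (ENSDARG00000017174, 1.76; ENSDARG00000079964, 0.43), syt1 (0.94) and isl2 (ENSDARG00000003971; 0.21), and ina (ENSDARG00000011862; 0.01), lhx1a (0.02) and isl1 (0.05) did not pass. With either control library left out 13 neuron genes were lower, with control replicate 1 left out 2 were higher, and with a minimum of 5 TPM the adjusted p of the list was 0.0625.

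Among 21 neural crest and pigment cell genes, 15 fell, 5 rose and 1 did not pass (15 and 5 adjusted over the list alone), while the list as a set did not pass (median -0.69, camera adjusted p = 0.0636; 0.0354 without mutant replicate 1). The crest genes crestin (-1.67, SE 0.117), sox9 (ENSDARG00000043923; -1.37, SE 0.088) and twist1a (-1.10, SE 0.073) fell. The purine metabolism gene pnp4a, a marker of iridophores, rose from 0.105 ± 0.0636 TPM to 6.78 ± 1.17 TPM (2.81, SE 0.153). Being under 1 TPM in both controls, it passed the filter only through the mutants and could enter only by rising. The other risers, named after their values were seen, were pax7 (ENSDARG00000070818; 0.94), which is also in the progenitor list, tfap2c (0.90), snai2 (0.64) and dlx3 (0.25), and kit had a log2 change of 0.04.

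Of 28 skeletal muscle genes, 20 fell, 2 rose and 6 did not pass (20 and 2 adjusted over the list alone; median -0.58, camera adjusted p = 0.000612, and adjusted p = 0.328 with an estimated correlation). The myosin light chain gene myl1 (ENSDARG00000014196) fell from 77.1 ± 2.45 TPM to 19.9 ± 1.13 TPM (-1.90, SE 0.073), the myogenic factor gene myf5 by 1.59 (SE 0.086) and the creatine kinase gene ckma by 1.57 (SE 0.085). Risers named after their values were seen were cav3 (0.85) and 1 copy of acta1 (ENSDARG00000036371; 0.22), and 1 of the 2 was counted with either control left out. Of 30 presomitic mesoderm and tailbud genes, 18 fell, 4 rose and 8 did not pass (18 and 4 adjusted over the list alone), and the list did not pass (median -0.51, camera adjusted p = 0.0653; 0.0424 without control replicate 2). The presomitic factor genes tbx6 (-0.87, SE 0.079) and mespab (-1.47, SE 0.138) fell, whereas the tailbud signal gene wnt8a (ENSDARG00000078507; 2.18, SE 0.144) and the retinoic acid degrading enzyme gene cyp26a1 (0.85, SE 0.071) rose. The remaining risers, named after their values were seen, were the second wnt8a entry (ENSDARG00000052910; 1.93) and mespbb (0.42). Among 23 notochord and floor plate genes, 6 rose, 5 fell and 12 did not pass (6 and 5 adjusted over the list alone). The list median (-0.08) and mean (-0.03) were below 0 while camera put the list above other genes (adjusted p = 0.748), and fry put it below 0 (adjusted p = 0.656). The laminin chain gene lamc1 (58.9 ± 0.636 TPM to 146 ± 6.77 TPM) and the floor plate factor gene foxa2 (1.31, SE 0.078) rose, and the heparin-binding growth factor gene mdk (ENSDARG00000036036) fell by 1.52 (SE 0.052). The other genes that fell, named after their values were seen, were the second mdk (ENSDARG00000020708; -1.20), col9a1 (2 to 0.495 TPM), loxl1 (-0.64) and foxa (-0.28); without control replicate 1 or 2 the number that fell was 3 or 2.

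Of 18 erythroid and blood progenitor genes, 12 fell, 3 rose and 3 did not pass (13 and 3 adjusted over the list alone; median -0.84, camera adjusted p = 0.0316, and adjusted p = 0.343 with an estimated correlation). The embryonic globin gene hbbe3 fell from 290 ± 28.1 TPM to 91.0 ± 8.67 TPM (-1.66, SE 0.094) and znfl2a by 1.89 (SE 0.078). The blood progenitor factor genes tal1 (1.22, SE 0.062) and lmo2 (1.36, SE 0.072) rose, as did klf17 (0.68). Values of the others, named after they were seen, were -0.53 for gfi1aa, -0.34 for 1 copy of slc4a1 (ENSDARG00000024560) and 0.08 for hbae1.1. The call of the erythroid list was lost without mutant replicate 2 (adjusted p = 0.0799), without control replicate 2 (0.0783) and with a minimum of 5 TPM (0.101). Of 11 myeloid genes, 7 fell, 2 rose and 2 did not pass (7 and 2 adjusted over the list alone), and the list did not pass (median -1.19, camera adjusted p = 0.0954). The cathepsin gene ctss2.1 (-1.85, SE 0.124) and the chemokine receptor gene cxcr4 (ENSDARG00000057633; -1.70, SE 0.085) fell, and cebpb rose by 0.85 (SE 0.061). Named after their values were seen, cebpa rose by 0.39, and irf8 (-0.23) and lcp1 (0.04) did not pass; with either control left out 4 myeloid genes were lower. Of 17 endothelial genes, 8 rose, 2 fell and 7 did not pass (8 and 2 adjusted over the list alone; median 0.29, camera adjusted p = 0.0415, and adjusted p = 0.328 with an estimated correlation). The apelin receptor gene aplnrb rose from 25.4 ± 0.544 TPM to 166 ± 16.7 TPM (2.66, SE 0.083) and the vascular factor gene sox7 by 1.98 (SE 0.080), while tek (-1.08, SE 0.128) and sox18 (-0.44, named after its value was seen) fell. With either control library left out 5 endothelial genes were higher. With control replicate 1 left out 1 was lower, with control replicate 2 left out 0 were lower, and under median ratio scaling 1 was lower.

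Of 28 epidermis and periderm genes, 16 rose, 5 fell and 7 did not pass (16 and 5 adjusted over the list alone; median 0.38, camera adjusted p = 0.000935, and adjusted p = 0.322 with an estimated correlation). The annexin gene anxa1 (ENSDARG00000026726) rose from 169 ± 12.5 TPM to 1115 ± 32.2 TPM (2.71, SE 0.064), and the claudin genes cldni (1.61, SE 0.054) and cldnb (0.98, SE 0.054) rose. The members that fell, named after their values were seen, were atp6v1a (ENSDARG00000076318; -1.52), foxi3b (-1.19), foxi3a (-1.18), tp63 (-0.34) and krt91 (-0.19), of which foxi3a and foxi3b specify ionocytes and atp6v1a encodes a proton pump subunit. Without control replicate 1 the number that fell was 3. Of 10 hatching gland genes, 8 rose, 1 fell and 1 did not pass (8 and 1 adjusted over the list alone; median 0.57, camera adjusted p = 0.0143, and adjusted p = 0.328 with an estimated correlation). The hatching enzyme genes he1.1 (2665 ± 47.4 TPM against 1623 ± 44.7 TPM; 0.72, SE 0.045) and he1.2 (0.71, SE 0.045) and the gland factor gene klf17 (0.68, SE 0.067) rose. Named after their values were seen, fbp1b fell by 0.65 and agr2 had a log2 change of -0.28. The number that rose was 5 without control replicate 2, and the number that fell was 2 without mutant replicate 2. Of 26 yolk syncytial layer and endoderm genes, 12 rose, 8 fell and 6 did not pass (12 and 8 adjusted over the list alone), and the list did not pass (median 0.24, camera adjusted p = 0.0698; 0.0136 without mutant replicate 1). The retinol carrier gene rbp4 (1.21, SE 0.053) and the lipoprotein gene apoeb (0.72, SE 0.039) rose, and apoa4b.1 fell by 0.80 (SE 0.046); with either control left out 4 members were lower, and under median ratio scaling 5 were.

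Of 34 heat shock and stress response genes, 17 rose, 3 fell and 14 did not pass (17 and 3 adjusted over the list alone; median 0.25, camera adjusted p = 0.00150, and adjusted p = 0.328 with an estimated correlation). The lowest p-values among the risers were those of the immediate early factor genes jun (39.1 ± 0.219 TPM to 205 ± 1.95 TPM; 2.36, SE 0.054), junb (ENSDARG00000104773; 3.59, SE 0.111) and atf3 (4.33, SE 0.142), and of hmox1, the heme-degrading oxygenase gene (2.17, SE 0.080). The members that fell, named after their values were seen, were txnrd3 (-0.76), atf4a (-0.70) and hsf1 (-0.28). Of 23 inflammation and interferon response genes, 12 were tested, of which 11 rose and 1 did not pass (11 and 0 lower adjusted over the list alone). The median was 1.22, with camera adjusted p = 1.16e-05, and adjusted p = 0.322 with an estimated correlation. Of those tested, isg15, ifit8, il11a and socs3 (ENSDARG00000025428) were under 1 TPM in both controls and passed the filter only through the mutants. These could enter only by rising, so the count, median and list test lean upward. Besides isg15, the interferon-induced gene ifit8 rose to 10.8 ± 0.566 TPM from 0.045 ± 0.0354 TPM (3.50, SE 0.121) and the cytokine signalling inhibitor gene socs3 (ENSDARG00000025428) rose by 3.11 (SE 0.163). The cytokine gene il11a was listed at 0 in both controls and at 10.1 and 11.6 TPM in the mutants, and irf1b had a log2 change of 0.22. With either mutant library left out, isg15, ifit8, il11a and this socs3 could not meet the filter and were not tested.

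Of the 22 lists, 16 passed camera with its preset correlation and 0 with an estimated correlation, for which 2 residual degrees of freedom remain; at an unadjusted p under 0.05 the p53 targets (p = 0.0316) and the inflammation genes (p = 0.0390) passed with it. By fry, which asks whether a list moves on balance without setting it against other genes, adjusted p ranged from 0.000389 to 0.0406 for 20 lists and was 0.0581 for glycolysis and 0.656 for the notochord and floor plate.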

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

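The alternatives were among the choices fixed in advance. Requiring a fold of at least 2 left 1543 genes higher and 1854 lower, by construction. With an estimated correlation the adjusted p was 0.322 for the p53 targets, the cell cycle inhibitors and apoptosis and 0.328 for the replication and mitosis lists; that test rests on 2 residual degrees of freedom. Among lists that passed with the preset of 0.01, the estimated correlation lay below it for the inhibitors (-0.0218), epidermis (-0.0241), inflammation (-0.0585) and endothelium (-0.0125). A higher correlation therefore did not end those calls. For the other lists that lost their call the estimate lay above the preset, from 0.0175 for the p53 targets to 0.673 for the replication genes. It was 0.464 for mitosis, 0.358 for repair, 0.337 for ribosome biogenesis and 0.289 for neural progenitors. The small adjusted p of the replication list and of these lists thus rests on a preset far below the estimate. How much of each loss came from correlation and how much from degrees of freedom was not separated. Under the other settings, with all 4 libraries, 3559 to 5293 genes were higher and 4609 to 6388 lower, the low ends with a 5 TPM filter that tests 11317 genes. Median ratio scaling gave 5293 higher and 5301 lower, 49.96% of calls higher against 42.61%, and shared all 4522 higher and 5301 of the lower calls. With 1 library left out, 3510 to 3902 genes were higher and 4169 to 6115 lower. The replicate block gave 4457 higher and 6062 lower; deviations of same-numbered libraries correlated at 0.0488 across genes, so the numbers were not taken to pair samples, and no list changed its side of the threshold under the block.

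Of 1299 values of 110 named genes under the alternatives, 1296 kept direction and side of the threshold, and 0 reversed. The exceptions were those of u3 (ENSDARG00000115704), with adjusted p of 0.0637 at a pseudocount of 0.1 TPM, 0.0676 without a filter and 0.0875 without control replicate 1. A gene that failed the filter under a setting gave no value there. Among the largest rises, cdkn2a/b, rgs20, rgs5b, cxcr3 and isg15 were under 1 TPM in both controls. They were therefore not tested with either mutant library left out. With the preset correlation, the p53, inhibitor, replication, mitosis and apoptosis lists kept their calls, with adjusted p up to 0.00944. Those that crossed the threshold were the neuron (0.0625) and erythroid (0.101) lists with a 5 TPM filter, the erythroid list without mutant replicate 2 (0.0799) or control replicate 2 (0.0783), the tailbud list without a filter (0.0235) or control replicate 2 (0.0424), the neural crest list without a filter (0.0224), with median ratio scaling (0.0366) or without mutant replicate 1 (0.0354), and the yolk list without mutant replicate 1 (0.0136). The cause was not tested. Of the list counts, 26 moved by over 1.5 times without 1 library and 13 under other settings. Depth is unknown, so its effect on low genes could not be measured.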

Other observations

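Of the tests reported here, the one on the neighbours of mdm2 was specified before its result was seen, and the others were chosen after the results were seen, as were the genes named in the next 2 paragraphs.

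Some genes outside the fixed lists also rose in the quadruple mutants. The fos transcript, which encodes a partner of jun, went from 2.15 ± 0.410 TPM to 88.2 ± 0.0990 TPM (SD, n = 2 per genotype; log2 change 4.83, SE 0.110), and fosl1 from 0.735 ± 0.0354 TPM to 36.3 ± 5.84 TPM (4.42, SE 0.135). nupr1a, a stress-induced chromatin protein gene, went from 106 ± 9.19 TPM to 2269 ± 58.4 TPM (4.41, SE 0.069). lgmn, which encodes the lysosomal protease legumain, went from 57.9 ± 1.32 TPM to 1324 ± 35.3 TPM (4.49, SE 0.051), and mat2al, a methionine adenosyltransferase gene, from 22.9 ± 1.00 TPM to 865 ± 2.09 TPM (5.18, SE 0.056). Similar changes were seen for phlda2 (4.72, SE 0.064) and igfbp7 (4.61, SE 0.094).

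The histone chaperone gene nasp went from 263 ± 4.48 TPM to 32.3 ± 8.12 TPM (-3.01, SE 0.156), and both copies of asf1b fell, by 2.81 (ENSDARG00000101037, SE 0.190) and 1.59 (ENSDARG00000043713, SE 0.128). The replication clamp gene pcna, a textbook p53 target in other species, had the smallest fall among the 54 members of its list that fell, from 1000 ± 4.41 TPM to 742 ± 16.5 TPM (-0.43, SE 0.044). On the age of the embryos, which the labels give as 18 hpf or 30 hpf, the segmentation clock genes her1 and her7 stood at 15.7 ± 0.368 and 13.6 ± 0.700 TPM in the controls and at 10.5 ± 1.58 and 8.64 ± 0.948 TPM in the mutants. With 1 stage sampled these values do not settle it.

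The fall of replication genes could partly reflect the share of TPM taken by the genes that rose, or a loss of neural progenitor cells. After median ratio scaling the median log2 change of the replication genes was still -2.055, which argues against the first. Neural progenitor genes had a median of -1.327, above that of the replication genes. Replication minus progenitor medians were -0.87 and -0.77 in mutant libraries 1 and 2, so the progenitor list fell less. The control values, 0.02 and -0.02, mirror each other by construction and are no separate baseline. The progenitor list is not specific to these cells, as pax7 is also in the neural crest list. It also holds low genes such as rx1, whose change the log2(TPM + 1) scale understates. The gap therefore does not decide whether loss of progenitors was the whole cause. Reduced proliferation across tissues remains a candidate biological explanation, and it was not tested by any measurement of cells.

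Within the mutants, library 2 lay above library 1 in 51 of 56 replication genes. A scaling difference between them is argued against, since genes with no call differed by a median of 0.03819 where replication genes differed by 0.257. A response weaker by the same log2 fraction is also argued against, since genes that rose at least 4-fold lost 2.671% of their response (95% bootstrap interval over genes, which are not independent, 2.07 to 3.45) and genes that fell at least 4-fold lost 13.14% (10.97 to 15.04). Control RNA in library 2 is a candidate explanation that the values fit only in part. The excess over library 1, as a share of the gap to the controls, had a median of 5.051% in 50 replication genes. It was 5.826% in 962 other fallen genes (permutation p of the difference 0.4871, over genes that are not independent), which does not show equal shares. Genes that rose at least 4-fold were lower as a group by the amount such a share predicts (-0.077 against -0.072), though mdm2 was higher. The excess was absent in 6 muscle genes (0.164%) and 4 erythroid genes (-2.62%), and was 8.08% in 18 neural progenitor genes. Mitochondrial transcripts held 1.28% of TPM in library 2, 0.93% in library 1 and 1.096% and 0.974% in the controls. Mixing a pool like library 1 with control RNA would not give that share. Embryos of milder state in the pool of library 2 may account for the excess as well, and this was not tested.

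The higher epidermis and hatching gland transcripts could follow from a lower share of neural cells, which would raise all other tissues alike. Muscle genes had a median of -0.5824, and muscle minus epidermis medians were -1.002 and -0.998 in mutant libraries 1 and 2, which argues against that explanation alone. The control values, -0.02 and 0.02, mirror each other by construction and are no separate baseline. A developmental delay cannot be told apart from a direct effect of genotype, because 1 stage was sampled; the presomitic and tailbud genes, which decline as embryos age, had a median of -0.5095. A changed share of surface tissue in the mutants stays open.

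Genes linked to mdm2, where variants of the mutant chromosome would be carried along, were not set apart as a group. The 25 tested genes on each side had a mean absolute log2 change of 0.644, at percentile 39.19 of 10000 windows of the same size elsewhere. Those windows had a median of 0.672 and a 95th percentile of 0.877, with 11572 genes placed. With change this broad over the genome, the mean could not show variants that alter only a few of these genes.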
